A study of Mus musculus with 99 samples.

How the data were processed

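Heart RNA of male mice was hybridised to Affymetrix HT_MG-430A arrays, 1 per strain, 99 in all. Per the labels, total RNA was reverse transcribed from an oligo-dT primer and labelled with biotin. The authors deposited log2 values for 22416 probe sets, 89 of them controls, and the submitters' processing notes name GCOS and RMA without versions. RMA corrects the background, normalises by quantiles and sums probes on the log2 scale, so the values already share a distribution between arrays. No scanner files were analysed here, so signal over background per array and probe-level effects could not be examined, and levels near 3 log2 units are close to the floor of the array.

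Strains were grouped by their names in the labels into classical inbred, BXD, AXB, BXA, BXH, CAST/EiJ and B6cC3-1/KccJ. The age label rises from 16 to 113 weeks, by 1 in 97 of 98 steps along the sample order, while the protocol in the labels gives 16 weeks for all, so the age label was not used. The titles are numbers whose meaning is not given in the sources used here. They run from 473 to 670 in BXD, 481 to 683 in AXB and 518 to 674 in BXA, which interleave, and from 3 to 394 in BXH and 40 to 456 in the classical strains. The plan took these last ranges to interleave, but 7 of the 11 BXH arrays come before the first classical strain and only 4 lie among them. Labels give no shared replicate numbers. The near-isogenic families AXB19, AXB19a and AXB19b and the BXD24 pair were averaged to 1 value each.

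Probe sets were named from the platform annotation: 17783 had 1 gene symbol, 284 several and 4349 none here. Of the first, 17759 matched the RefSeq gene table by Entrez identifier, which changed 0 symbols. Probe sets with several symbols or none were not named. The brightest probe set stood for each of the 11725 genes. Genes with a mean above the 40th percentile of all probe sets (3.59 log2 units) were kept, which left 7513. No genome build is given in the sources used here, so no coordinates are printed.

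Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without covariates, only the compared groups in each fit), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, then with an estimated correlation and with fry. Of 505 entries in 27 lists, 409 were on the array. Older names were updated, and a current symbol was never read as an older name of another gene. This last point corrected glycolysis entries that had been matched to other genes. It was made after the results had been seen and changed no call of a list or relation. Only lists with at least 4 tested genes were used. The unadjusted test of 7513 genes gives 375.65 with p under 0.05 by chance. Named genes followed a rule: per comparison the 10 largest called differences in each direction and up to 4 called members of each called list, called members of the lists of known strain variants and Y-linked genes, the 20 genes of largest SD, up to 8 segregating genes per panel, 6 genes on each side for CAST/EiJ, the genes of the fixed relations, and Cep290 and Tlr4 as label checks. Other genes, such as Alb, Myl2 and single uncalled members, were chosen after their values were seen.

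Panel differences were correlated with parental differences over all 756 ordered pairs of classical strains, and the SD within panels with parental differences over 27 candidate strains. Correlations across strains were tested by 100000 permutations, two-sided. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table (version 1.17.8), were also used. The grouping, tests, lists, relations and most alternatives were fixed before the data were examined. The liver, squamous epithelium and thyroid lists, the level of 2 log2 units, the correlation of 0.5 that defines a gene following such a list, the arrays left out and the control covariates were added after the data were seen.

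Limma, camera, the parental pair, the segregation, the range of a single strain and the correlations were tested on simulated data. Fry and the list spread were not, and the outcome for camera is not given here. For limma the data had 7513 genes and 67, 67 and 66 genes changed by 0.25, 0.5 and 1 log2 units. Limma recovered 67.2%, 94.0% and 95.5% of them for BXD against AXB and BXA (7 false calls), 37.3%, 91.0% and 97.0% for AXB against BXA (8), 31.3%, 82.1% and 100.0% for BXH against the classical strains (4) and 38.8%, 95.5% and 100.0% for BXH against BXD (12). The simulated parents ranked 1 of 756 pairs and 1 of 27 strains, and a shifted strain 1 of 29. The simulated panels took their values from the parental arrays themselves with a small error added. Their rho was 0.940 for the pair and 0.915 for the segregation, against 0.480 and 0.355 in BXD in the data. These parental ranks therefore do not show recovery at the noise of the real data. A related pair had r = 0.884 (permutation p = 1e-05) and an unrelated pair a permutation p of 0.402. Alternatives covered the filter, quantile normalisation on top of the deposited values, the mean over probe sets, array weights, the variance prior, separate near-isogenic strains, the title number, left-out arrays and genes, and the control probe sets.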

Results

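Transcript levels were measured in the hearts of male mice fed a chow diet, with 1 Affymetrix HT_MG-430A array per strain, for a genome-wide association study of expression in inbred strains. The 99 arrays covered 28 classical inbred strains, 30 BXD, 15 AXB, 13 BXA and 11 BXH recombinant inbred strains, the wild-derived strain CAST/EiJ and the strain B6cC3-1/KccJ. A recombinant inbred strain is a homozygous mosaic of its parents, which are C57BL/6J and DBA/2J for BXD, C57BL/6J and A/J for the reciprocal panels AXB and BXA, and C57BL/6J and C3H/HeJ for BXH. Near-isogenic strains were averaged, which left 29 BXD and 13 AXB families. No strain had a replicate array, so each error and p-value below measures the spread between strains, technical spread included. The deposited log2 values ran from 2.40 to 13.695, the array medians from 3.97 to 4.07, and 7513 genes passed the filter on dim genes. The number of arrays, not a count depth, limits the precision.

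Among the classical strains, transcripts of airway, fast skeletal muscle, antigen presentation, red blood cells, interferon response and fat tissue varied most, while those of mitochondrial respiration varied least. The median over genes of the SD between the 28 strains was 0.23 log2 units (jackknife SE 0.0057), beside 0.20 within the near-isogenic families (0.15 without AXB19/PgnJ), and 91 genes had an SD of at least 1. The within-family SD rests only on the AXB19 strains and the BXD24 pair. A median SD from so few arrays runs low, so these medians are not measured alike. The largest SD belonged to Scgb1a1 (3.25), the main secretoglobin of airway club cells, followed by Bpifa1 (3.07), a secreted airway protein, Gdpd3 (3.04), a lysophospholipase D, and Hamp2 (2.64), a copy of the hepcidin gene. Gdpd3 lay more than 1 log2 unit above the median strain in 10 strains. Pdxdc1, with a pyridoxal-dependent decarboxylase domain, lay more than 1 below it in 7. The epithelial keratin Krt4 (2.59), the cornified envelope protein Lor (2.00) and adenosine deaminase Ada (2.35) each exceeded the median by more than 1 in 3 strains and peaked in 129X1/SvJ. So did the fast muscle genes Tnnc2 (1.97) and Myh1 (1.78), whose medians of 3.29 and 3.09 lay near the floor.

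The gene lists differed in this spread, read against 10000 random lists of the same size and mean level. The antigen presentation list had a median SD of 0.84 (12 genes), erythroid 0.74 (5), interferon response 0.67 (19), adipocyte 0.67 (9), lung and airway 2.22 (7), skeletal muscle 1.20 (11) and immediate early genes 0.51 (14), each above all of the random lists. The oxidative phosphorylation list had a median SD of 0.083 over 44 genes, below all of them (random median 0.13). Ribosomal protein genes lay at percentile 1.04 (0.12, 21 genes) and sarcomere genes at 16.7 (0.12, 19 genes). These percentiles describe these arrays and test no difference.

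Marker transcripts of other organs reached high levels on 30 of the 99 arrays, defined as a list mean more than 2 log2 units above the median array. The lung and airway list passed this level on 19 arrays, the liver list on 9, squamous epithelium on 7, skeletal muscle on 6, thymus on 2 and thyroid on 1. The airway list passed it in 8 of 11 BXH, 4 of 28 classical, 3 of 30 BXD, 3 of 15 AXB and 0 of 13 BXA arrays. Across all arrays Scgb1a1 ran from 3.02 to 13.04, the serum protein gene Alb from 3.00 to 13.09 and Krt4 from 2.83 to 11.80. The ventricular myosin light chain Myl2 stayed between 13.39 and 13.65. That is close to the highest deposited value, 13.695, so its narrow range may reflect this ceiling and does not measure the share of heart RNA. The liver, squamous epithelium and thyroid lists, the level of 2 log2 units and the arrays left out by it were chosen after the values had been seen.

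**Figure D1:**
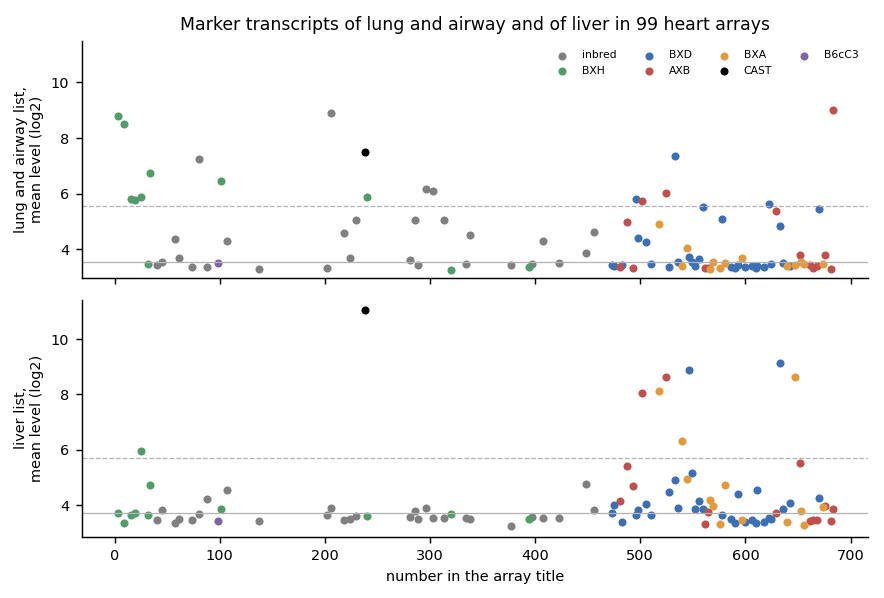
Mean log2 level of the lung and airway list (upper panel) and of the liver list (lower panel) on each of the 99 arrays, against the number in the array's title, coloured by strain group. Solid lines mark the median array and dashed lines 2 log2 units above it, a level passed by 19 and 9 arrays.

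BXD hearts were compared with AXB and BXA hearts, which sets DBA/2J against A/J alleles on a shared C57BL/6J background. BXD hearts had higher levels of Hamp2 (2.39, SE 0.58, 5.23-fold) and of Hamp (1.72, SE 0.32, 3.29-fold), which encodes the iron-regulating peptide hepcidin. Sfi1 (2.00, SE 0.31), which encodes a centrin-binding centrosome protein, was higher as well. Bcat2, the mitochondrial aminotransferase of branched-chain amino acids, was 3.19-fold higher (1.68, SE 0.29). Lower in BXD were Baiap2l1, an actin-bundling adaptor (-3.16, SE 0.42, 8.95-fold), Pdxdc1 (-2.62, SE 0.48) and Abhd1, a hydrolase (-1.73, SE 0.33). The immediate early nuclear receptor Nr4a1 (-1.20, SE 0.23) and the fast myosin light chain Myl1 (-1.08, SE 0.19) were also lower.

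Of the 7513 genes, 1099 differed between the 29 BXD and 26 AXB and BXA families with adjusted p under 0.05 in limma, 645 higher and 454 lower in BXD. The median size of these differences was 0.21 log2 units, and 20 genes differed by at least 1. The smallest adjusted p belonged to Dnajc10, a chaperone of the endoplasmic reticulum (1.12, SE 0.12, adjusted p = 5.13e-10). The remaining large differences were higher in BXD for Phkg1, Stab2, Cap1, Rbp7 and Ocel1 (1.09 to 1.20), and lower for Erdr1 (-1.47), Ift81 (-1.18), Gbp2b (-1.17), Nipsnap2 (-1.11) and Zfp277 (-0.97). Adjusted p was 0.00310 for Hamp2, 0.000137 for Hamp, 3.35e-07 for Baiap2l1 and 0.000104 for Pdxdc1. The near-identical copies Hamp and Hamp2 are hard to separate by hybridisation, and the other Hamp2 probe set differed by 0.03. Another Pdxdc1 probe set differed by 2.76 in the opposite direction.

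**Figure D2:**
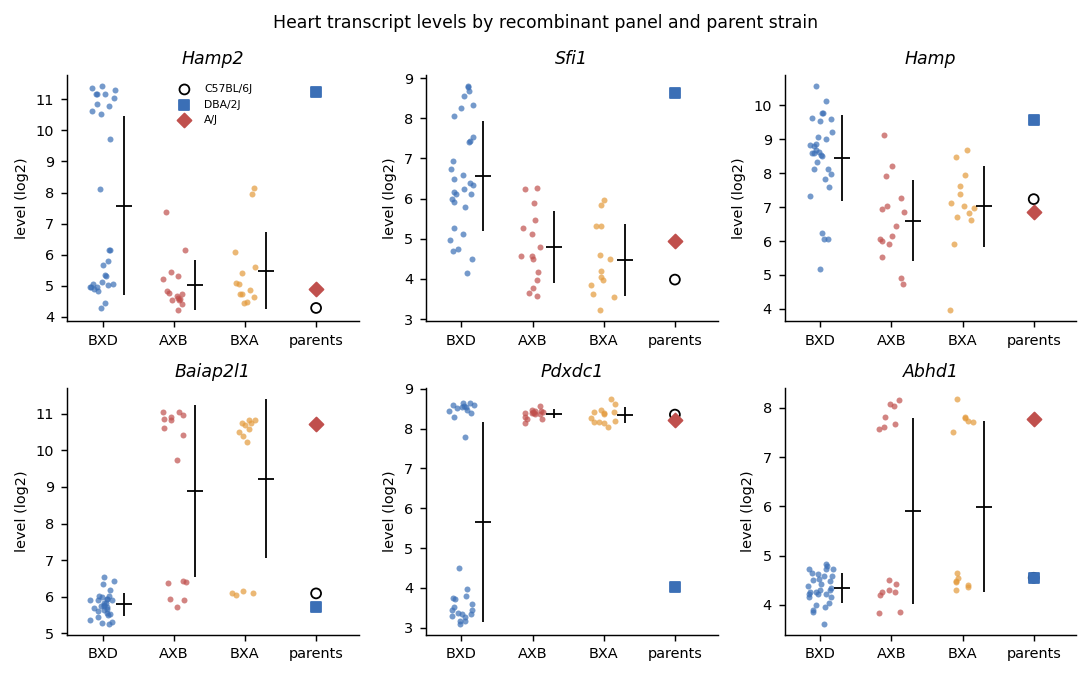
Log2 levels of 6 genes on each BXD (30), AXB (15) and BXA (13) array, with the mean and SD of each panel, and on the single arrays of the parents C57BL/6J, DBA/2J and A/J. Baiap2l1 in AXB and BXA falls into a low (5.71 to 6.42) and a high range (9.73 to 11.06).

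Among gene lists, endothelial markers were higher in BXD (camera adjusted p = 0.000701), with 5 of 13 higher, none lower and 8 called when adjusted over the list alone. Emcn (0.35), Flt1 (0.33), Cdh5 (0.30) and Eng (0.22) were among the 5, and the list had an adjusted p = 0.644 with an estimated correlation. Antigen presentation genes were higher (adjusted p = 0.0400), with 3 of 12 called, H2-T23 (1.06), H2-T10 (0.77) and H2-Ea (0.27), and 3 adjusted over the list alone. Another H2-Ea probe set differed by 2.55 in the same direction, and the other H2-T23 probe set by -0.08. That list had an adjusted p = 0.721 with an estimated correlation. Interferon response genes were higher (adjusted p = 0.0410), with Gbp2 (0.68) and Ifit3 (0.67) called among 19 genes, also 2 adjusted over the list alone, and that list had an adjusted p = 0.802 with an estimated correlation. Without the arrays with markers of another organ the interferon and erythroid lists were not called (adjusted p = 0.0728 and 0.124). The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA quality, was -0.22 ± 0.08 (SD, 30 BXD arrays) and -0.31 ± 0.08 (28 AXB and BXA arrays). With it as a covariate, an alternative added after the data were seen, the endothelial, antigen presentation and interferon lists had an adjusted p = 0.147, an adjusted p = 0.0812 and an adjusted p = 0.169. Their medians moved from 0.18 to 0.046, from 0.13 to 0.087 and from 0.15 to 0.088. The list of known strain variants, lower in BXD, was called with that covariate (adjusted p = 0.0331) and not without it (0.0501). It had an adjusted p = 0.544 with an estimated correlation and no covariate.

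Respiratory chain genes were lower in BXD (camera adjusted p = 0.000117), with 5 of 44 lower and none higher, also 5 adjusted over the list alone, and an adjusted p = 0.644 with an estimated correlation. The differences were small, as for the complex I subunits Ndufs4 (-0.14) and Ndufs1 (-0.081), the oxidase subunit Cox5a (-0.074) and the ATP synthase subunit Atp5g1 (-0.071). Immediate early genes were lower (adjusted p = 0.0258), with Nr4a1 and Dusp1 (-0.39) called among 14, also 2 adjusted over the list alone, and an adjusted p = 0.721 with an estimated correlation. Erythroid genes were lower (adjusted p = 0.0393), with 0 of 5 called by limma, 2 adjusted over the list alone, a median difference of -0.26 and an adjusted p = 0.721 with an estimated correlation. The test fry, which asks whether genes of a list move one way, called the endothelial and respiratory lists and a list of known strain variants (adjusted p = 0.00507, 0.0174 and 0.00507), which had an adjusted p = 0.644, 0.644 and 0.544 in camera with an estimated correlation. In that last list Nnt (-0.31) and Tlr4 (-0.51) were lower and H2-Ea was higher. Nnt encodes the mitochondrial transhydrogenase that is mutated in C57BL/6J, and Tlr4 the endotoxin receptor. Alad, Apoa2, Dysf, Glo1 and Hc did not pass, nor did the Y-linked Eif2s3y (0.09), Kdm5d (-0.02) and Uty (-0.08). Median, mean and test differed in sign for 7 uncalled lists, such as the atrial and macrophage lists.

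Lower and upper ranges of the title numbers gave 385 genes (15 against 12 families, 343 of them among the 1099) and 156 genes (14 against 14, 149 shared), with fewer families in each. Leaving out the arrays with markers of another organ gave 635 genes (21 against 19 families, 580 shared), and the Gapdh and actin controls as covariates gave 405 genes (362 shared) and 567 genes (528 shared).

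The panel differences were set against those of the parent strains, DBA/2J minus A/J, measured on other arrays. Of the 1099 genes, 968 (88.1%) had the sign of the parental difference, which included 19 of the 20 that differed by at least 1 log2 unit. Hamp2 differed by 6.31 between the parents, Sfi1 by 3.68, Bcat2 by 3.98, Baiap2l1 by -5.00 and Pdxdc1 by -4.19. Nr4a1, lower in BXD, differed by 0.64 the other way. Across genes, which are not independent replicates, Spearman's rho between panel and parental differences was 0.480, the highest among all 756 ordered pairs of classical strains. The next pair, DBA/2J minus BTBR T<+> tf/J, had 0.404, and the highest share of signs in any other pair was 82.3%. The Gapdh control difference was -0.22 on the DBA/2J array and -0.37 on that of A/J, the direction of the panels. The share of signs and rho therefore cannot tell inheritance from RNA quality.

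**Figure D3:**
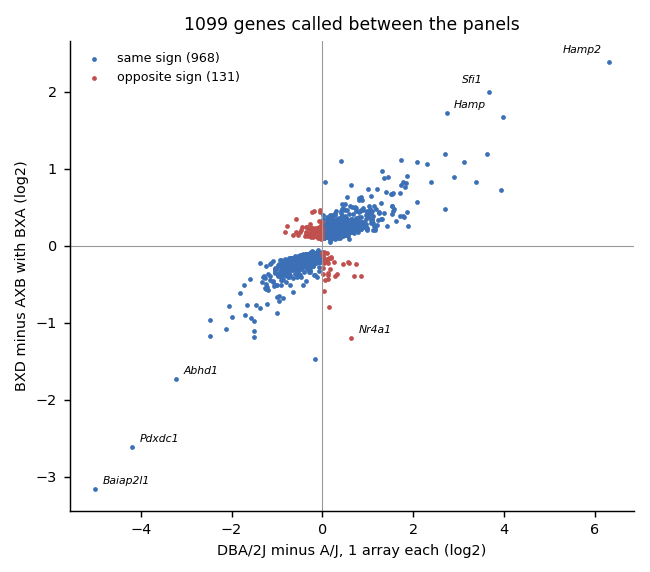
BXD minus AXB with BXA (log2, mean of families) against DBA/2J minus A/J (log2, 1 array each) for the 1099 called genes. Blue points share the sign (968 genes) and red points do not (131), with Hamp2, Sfi1, Baiap2l1 and Pdxdc1 far along the diagonal and Nr4a1 off it.

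Within panels, genes that differed between the parents also varied more between strains. Hamp2 was 4.29 in C57BL/6J and 11.22 in DBA/2J, and 13 of 29 BXD families lay above the midpoint. Pttg1, which encodes the anaphase inhibitor securin, was 11.92 and 5.81 in these parents, with 12 of 29 BXD families above the midpoint. Baiap2l1 was 6.09 in C57BL/6J and 10.72 in A/J, with 16 of 26 AXB and BXA families above. In BXH, 5 of 11 strains lay above the midpoint for Rpgrip1, a ciliary protein of photoreceptors, 7 for the carbonic anhydrase Car3 and 7 for Abhd1. Parents differed by at least 1 log2 unit at 342 genes in BXD, 204 in AXB and BXA and 342 in BXH. The median SD in the panel was then 0.46, 0.59 and 0.46, against 0.21, 0.20 and 0.21 for all other genes. Among genes whose parents differed by at least 1, the airway gene Scgb1a1 had the largest SD in BXD (3.00) and in AXB with BXA (3.05). It was 12.36 on the DBA/2J array and 9.90 on the A/J array, against 3.39 on that of C57BL/6J.

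Across genes, the SD within a panel correlated with the absolute difference of its parents (Spearman's rho 0.355 in BXD, 0.381 in AXB with BXA, 0.374 in BXH). With the other classical strains the median rho was 0.323, 0.317 and 0.278, so most of each value was not particular to the parents. Ranked among 27 candidate strains in place of the true parent, A/J and C3H/HeJ came at rank 1 for their panels and DBA/2J at rank 2, below CBA/J (0.357). DBA/2J came at rank 1 under 3 of the 6 other settings, and A/J at rank 5 with no filter on dim genes (0.365).

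**Figure D4:**
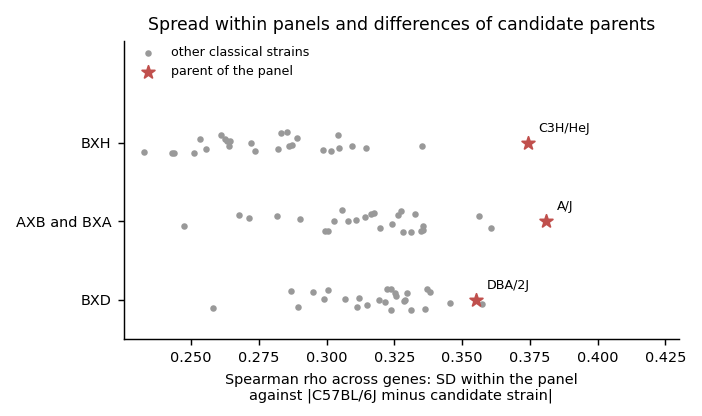
Spearman's rho, across genes, between the SD within a panel and the absolute difference between C57BL/6J and each of 27 classical strains. Stars mark the true parent, at rank 2 in BXD and rank 1 in AXB with BXA and in BXH.

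AXB and BXA strains come from the same parents crossed in opposite directions, so the Y chromosome and the mitochondria are the fixed differences between them. No gene differed between the 13 AXB and 13 BXA families in limma, while 786 genes had an unadjusted p under 0.05, against 375.65 expected by chance. Among lists, camera found endothelial markers higher in AXB (adjusted p = 0.000658, median 0.15), with adipocyte (0.0495, median 0.37) and airway genes (0.0137, median 1.18). With an estimated correlation these had an adjusted p = 0.551, 0.8001 and 0.8001. Ion channel and calcium handling genes (0.00102, median -0.092), glycolysis (0.00256, median -0.063) and oxidative phosphorylation (0.0195, median -0.014) were lower, with an adjusted p = 0.158, 0.551 and 0.8001 with an estimated correlation. No member of these lists was called over all genes, and adjusted over the list alone the count was 1 for the ion channel list and 0 for the others. The test fry called 0 lists. Airway markers passed the level of 2 log2 units in 3 AXB and 0 BXA arrays, and without the arrays with markers of another organ (10 against 9 families) only the endothelial list stayed called (adjusted p = 0.00226). The median and mean of the antigen presentation and the antioxidant list, neither of them called, differed in sign.

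BXH hearts were compared with the 28 classical strains, where 7 of the 11 BXH arrays have title numbers below those of all classical strains, so panel and title number largely coincide. BXH hearts had higher levels of Pttg1 (2.71, SE 0.58, 6.54-fold, adjusted p = 0.0218), of the glycogen-binding protein Stbd1 (0.92, SE 0.19) and of Plbd1, a phospholipase B domain protein (0.85, SE 0.19). Pttg1 was 11.92 in C57BL/6J and 7.76 in C3H/HeJ, the parents of BXH, and the BXH mean of 9.87 lay between them. Lower in BXH were Tmem87a (-1.30, SE 0.30), the vesicle coat subunit Copz2 (-1.28, SE 0.27), the zinc finger gene Zfp30 (-1.22, SE 0.26) and Dysf (-0.77, SE 0.13, adjusted p = 0.00233), the membrane repair protein dysferlin. Unlike Pttg1, Dysf had a BXH mean (5.57) below both parental arrays, 5.83 in C57BL/6J and 6.11 in C3H/HeJ. Limma called 22 genes, 6 higher and 16 lower in the 11 BXH strains, and 849 had an unadjusted p under 0.05. Strn, Erlec1 and Cyb5b were also higher (0.41 to 0.48). Frg1 (-0.79), Lyplal1 (-0.76), Stc2 (-0.59), Slc35f5 (-0.58), Xrcc5 (-0.56) and Hebp1 (-0.51) were also lower.

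Airway genes were higher in BXH as a list (camera adjusted p = 5.82e-05, median 1.56), with 0 of 7 called over all genes, 4 adjusted over the list alone and an adjusted p = 0.336 with an estimated correlation. Fatty acid oxidation (adjusted p = 0.00121, 23 genes), antioxidant (0.00742, 23 genes), macrophage (0.0128, 14 genes) and interferon response genes (0.0347, 19 genes) were also higher, and immediate early genes lower (0.0127, 14 genes). With an estimated correlation the antioxidant list had an adjusted p = 0.227 and the 4 others an adjusted p = 0.606, and fry called 0 lists. None of their members was called over all genes, and 0, 2, 0, 3 and 1 were when adjusted over the list alone. Median, mean and test differed in sign for uncalled lists, such as the atrial and ribosomal lists. Airway markers passed the level of 2 log2 units in 8 of the 11 BXH arrays and 4 of the 28 others. Without the arrays with markers of another organ (3 BXH against 23 classical strains) limma called 2 genes, 0 of them among the 22, and camera 0 lists. With the title number as a covariate 2 of the 22 were called. Below and above the median title number the counts were 0 (8 against 11 strains) and 4 (3 against 17, 0 of them among the 22), while arrayWeights and leaving out C57BL/6J and C3H/HeJ gave 58 genes each, the 22 included.

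BXH and BXD hearts were compared last, where title numbers do not overlap (3 to 394 in BXH, 473 to 670 in BXD), so panel and whatever the title numbers follow cannot be told apart. Airway transcripts led the genes higher in BXH, with Scgb1a1 (4.29, SE 1.11, 19.5-fold), Bpifa1 (3.83, SE 1.01), Scgb3a2 (3.64, SE 0.84) and the club cell cytochrome Cyp2f2 (3.25, SE 0.75). Baiap2l1 (3.56, SE 0.40, 11.8-fold) and Abhd1 (2.32, SE 0.33) were also higher. Lower in BXH were Hamp2 (-2.85, SE 0.85), the antitrypsin gene Serpina1b (-2.30, SE 0.62), Sfi1 (-1.66, SE 0.47) and the skeletal alpha-actin gene Acta1 (-1.28, SE 0.31). Without the arrays with markers of another organ, Scgb1a1 differed by -0.65 and Bpifa1 by -0.18 and neither was called.

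Limma called 799 genes, 323 higher and 476 lower in the 11 BXH strains against 29 BXD families, 28 of them by at least 1 log2 unit. Scgb3a1, Ltf, Cbr2 and Igkj1 were higher by 1.85 to 2.75 and the surfactant gene Sftpd by 1.0015, and Copz2 (-1.39), Fblim1 (-1.29), Parp3 (-1.10), Pam (-0.999), Tmem71 (-0.85) and Nfia (-0.78) were lower. Among known strain variants the haem synthesis gene Alad (0.85) was higher, and Dysf (-0.32) and the class II gene H2-Ea (-0.39) were lower. Another H2-Ea probe set differed by -2.58, while the other Hamp2 probe set differed by -0.02 and the other Parp3 probe set by -0.25. Of the 799 genes, 563 (70.5%) had the sign of C3H/HeJ minus DBA/2J, and 14 of the 28 that differed by at least 1. The DBA/2J array itself carried airway transcripts (list mean 7.25, Scgb1a1 12.36), unlike that of C3H/HeJ (3.44). Counts made after the data were seen set apart the genes that correlated at 0.5 or more with a marker list of another organ over the recombinant arrays. Of the 28 genes, 13 followed the airway list, and 12 of these had the opposite sign, such as Scgb1a1 and Bpifa1. Among genes that followed no such list, 12 of 14 of this size and 546 of all 748 (73.0%) had the parental sign. The correlations ran over the BXH and BXD arrays too, so the panel difference itself helped decide which genes were set apart. These shares are therefore not independent of that choice. Spearman's rho with that parental difference was 0.232, at rank 73 of the 756 pairs.

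Macrophage genes were higher in BXH (camera adjusted p = 2.49e-14), with 11 of 14 higher, none lower, 12 adjusted over the list alone and an adjusted p = 0.0625 with an estimated correlation. They included the signalling adaptor Tyrobp (0.95), the complement gene C1qa (0.80), lysozyme Lyz2 (0.65) and the growth factor receptor Csf1r (0.45). Ribosomal protein genes were higher (adjusted p = 3.74e-07), with 6 of 21 higher, 14 adjusted over the list alone and an adjusted p = 0.166 with an estimated correlation, such as Rps19 (0.20), Rpl8 (0.16), Rps14 (0.15) and Rpl4 (0.12). Airway genes were higher (adjusted p = 1.79e-05), with 4 of 7 called and 7 adjusted over the list alone, and erythroid genes likewise (0.00170), with 1 of 5, Alas2 (0.90), and 5 adjusted over the list alone. With an estimated correlation these had an adjusted p = 0.166 and an adjusted p = 0.321. Fatty acid oxidation genes were higher as a list (0.0229), with 2 of 23 higher, Angptl4 (0.91, other probe set 0.02) and Acot2 (0.51), 1 lower, the regulator Ppara (-0.68), 3 adjusted over the list alone and an adjusted p = 0.641 with an estimated correlation. Sarcomere genes were lower (0.00170), with 6 of 19 lower, 10 adjusted over the list alone and an adjusted p = 0.166 with an estimated correlation, such as Des (-0.25), Tnnc1 (-0.14), Ttn (-0.12) and Tpm1 (-0.10). Circadian clock genes were lower (0.0229), with 5 of 15 lower and 9 adjusted over the list alone, such as Per3 (-0.75), Per1 (-0.61), Tef (-0.57) and Usp2 (-0.34). That list had an adjusted p = 0.245 with an estimated correlation and an adjusted p = 0.581 without the arrays with markers of another organ. It holds genes that ran opposite across strains, such as Dbp and Arntl, so its direction need not hold for each member.

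The test fry called all of these lists but fatty acid oxidation and also an adrenergic and angiotensin list (adjusted p = 0.0467), for which camera gave 0.173, and 0.335 with an estimated correlation. For the uncalled list of known strain variants median and mean differed in sign. Airway markers passed the level of 2 log2 units in 8 of 11 BXH and 3 of 30 BXD arrays, and the Gapdh control difference was -0.31 ± 0.11 (SD, 11 BXH arrays) against -0.22 ± 0.08 (30 BXD arrays). Without the arrays with markers of another organ (3 against 21 families) limma called 66 genes, 50 of them shared, and camera called the macrophage (adjusted p = 2.96e-05) and erythroid lists (0.000623), while the airway (0.581), ribosomal (0.291), sarcomere (0.156), circadian (0.581) and fatty acid lists (0.222) were not called. Endothelial genes (lower, 0.00311) and immediate early genes (higher, 0.0159) were called there by camera and not with all arrays (adjusted p = 0.169 and 0.263, each 0.736 with an estimated correlation). With the Gapdh control as a covariate 513 genes were called, 409 of them shared. All 7 lists stayed called with it, and atrial genes (higher, adjusted p = 0.0290) and oxidative phosphorylation genes (lower, adjusted p = 0.0499) were called in addition. With an estimated correlation and no covariate these had an adjusted p = 0.641 and an adjusted p = 0.736.

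CAST/EiJ, a wild-derived strain with 1 array, was set against the range of the 28 classical strains. Liver transcripts stood highest above that range: the urea cycle genes Cps1 (11.49, classical mean 3.10 ± 0.19 SD, n = 28) and Arg1 (11.78 against 3.37), the tyrosine aminotransferase Tat, the apolipoprotein Apoc3, the fibrinogen gene Fgb and the haem carrier Hpx. Alb was 13.09 in CAST/EiJ, against a median of 4.58 over all arrays. Farthest below the range were Prxl2b (3.58 against 9.70 ± 0.27) and the mitochondrial ribosomal gene Mrpl39 (4.50 against 10.53 ± 0.20). Plpbp, Clns1a, the complex I gene Ndufa5 and the interferon-inducible GTPase Iigp1 followed. Of all tested genes 16.9% lay below the range and 10.6% above it. Of the 24 lists, 13 had a larger share below than all genes, largest for erythroid (3 of 5) and interferon response genes (8 of 19), and 6 had none below. The share above was larger in 11 lists, largest for skeletal muscle (7 of 11) and antioxidant genes (7 of 23), and 6 lists had none above. Whether these shares exceed that of all genes was not tested.

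CAST/EiJ lay outside the range of the other strains at 2064 of 7513 genes (27.5%), 794 above and 1270 below. Chance alone gives a strain 6.90% of genes, and the classical strains had a median of 437 and at most 968 (LP/J). CAST/EiJ ranked 1 of 29 strains, an exact p of 0.0345, which is the smallest this design allows. A distance of at least 0.5 log2 units left 496 genes, 240 above and 256 below.

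**Figure D5:**
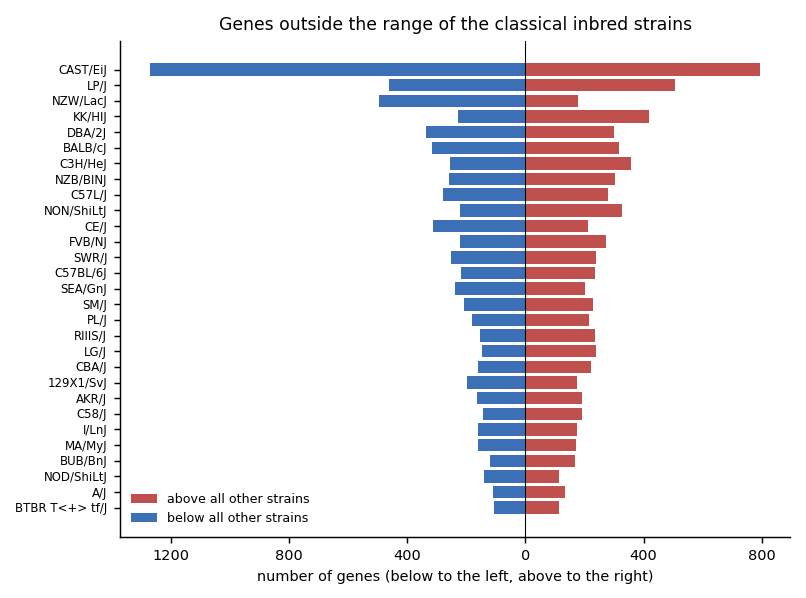
Number of genes, of 7513, at which CAST/EiJ or a classical inbred strain lies above (right) or below (left) the range of all other strains in the plot. CAST/EiJ lies outside at 2064 genes and LP/J, the next, at 968.

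Fixed pairs of genes and lists were correlated across strains within 4 panels, 32 relations in all, of which 16 had an adjusted p under 0.05 for Pearson's r. The clock output gene Dbp ran opposite to the clock activator Arntl in each panel (r = -0.900 in 28 classical strains, -0.888 in 29 BXD, -0.907 in 26 AXB and BXA, -0.856 in 11 BXH). In the classical strains Spearman's rho was -0.882 and the permutation p was 1e-05, the smallest 100000 resamples can give (adjusted p = 4.57e-05), and r was -0.873 without the 2 strains farthest from the median of Dbp. The immediate early genes Fos and Egr1 rose together (r = 0.771, 0.647, 0.849 and 0.879). In the classical strains rho was 0.727, the permutation p was 1e-05 (adjusted p = 4.57e-05) and r was 0.653 without the 2 farthest strains. In BXH that relation was lost without them (r = 0.705, adjusted p = 0.0657, 11 strains before, permutation test).

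The atrial peptide gene Nppa followed the atrial myosin light chains Myl7 and Myl4 (r = 0.722, 0.783, 0.952 and 0.820 in the same order). In the classical strains rho was 0.706, the permutation p was 3e-05 (adjusted p = 0.00012) and r was 0.635 without the 2 farthest strains, while in BXH r was 0.631 without them (permutation test, 9 strains left, adjusted p = 0.110) and rho with them 0.843. Nppa and the ventricular stress peptide Nppb were related in the classical strains (r = 0.559, rho 0.586, permutation p = 0.00187, adjusted p = 0.00460, r = 0.570 without the 2 farthest). In BXD that relation was called without the 2 farthest strains (r = 0.498, adjusted p = 0.0225) and not with them (r = 0.229, adjusted p = 0.321). Matrix and macrophage lists were related in AXB with BXA (r = 0.518, rho 0.528, permutation p = 0.00667, adjusted p = 0.0153, r = 0.492 without the 2 farthest). In the classical strains they were called without the 2 farthest strains (r = 0.493, adjusted p = 0.0275) and not with them (r = 0.399, adjusted p = 0.0657). Fatty acid oxidation and glycolysis lists ran opposite in the classical strains (r = -0.463, rho -0.478, permutation p = 0.0127, adjusted p = 0.0270), where r was -0.350 without the 2 farthest strains (adjusted p = 0.131). Nppb and the myosin gene Myh7 ran opposite in BXH (r = -0.678, rho -0.618, permutation p = 0.0222, adjusted p = 0.0444). The relation was not called by rho (adjusted p = 0.0813), after quantile normalisation (r = -0.607, adjusted p = 0.119) or without the 2 farthest strains (r = -0.422, adjusted p = 0.348). Whether relations differ between panels was not tested.

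Near-isogenic strains and mutant strains served as label checks. BXD24/TyJ and BXD24/TyJ-Cep290<rd16>/J lay on the same side of the parental midpoint at 85.4% of 342 genes, against a median of 65.1% and at most 74.3% with other BXD strains. AXB19a/PgnJ and AXB19b/PgnJ did so at 76.5% of 204 genes, against at most 73.0% for AXB19a/PgnJ with other AXB and BXA strains. AXB19/PgnJ shared 64.2% and 63.2% with these relatives, against a median of 53.9% and at most 63.2% with the other strains. Its deviations over all genes correlated weakly with theirs (r = 0.0926 and 0.0453), below its highest value with another strain (0.241). For AXB19a/PgnJ its share lay inside that with other strains (median 62.3%), so these values leave the label of AXB19/PgnJ open. The AXB19/PgnJ array also carried thymus transcripts (list mean 7.40), whose effect on these correlations was not tested. Tlr4 was 4.09 in BXD29-Tlr4<lps-2J>/J and 5.03 ± 0.26 (SD, n = 29) in the other BXD arrays, where the lowest was 4.42. In C3H/HeJ, whose Tlr4 mutation changes the protein, it was 5.4 against 5.43 ± 0.37 (SD, n = 27). Cep290 lay under the filter on dim genes (2.94 in the rd16 strain) and checks nothing.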

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

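The counts in this part lie outside the compared genes and strains, and they were computed after the comparisons had been seen. Among the 2523 probe sets with several gene symbols or none that passed the filter, limma called 378 between BXD and AXB with BXA, 199 higher and 179 lower, 11 of them by at least 1 log2 unit. That is 14.98%, beside 14.6% of the named genes. Between BXH and BXD it called 225, 96 higher and 129 lower (8.92%, beside 10.6% of the named genes). It called 3 between BXH and the classical strains and 0 between AXB and BXA.

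B6cC3-1/KccJ, which entered no comparison, lay outside the range of the 28 classical strains at 329 genes, 159 above and 170 below. Each classical strain set against the other 27 lay outside at 258 to 1130 genes (median 509.5), and 25 of the 28 reached 329 or more. The deviations of B6cC3-1/KccJ from the mean of all arrays correlated most with those of C57BL/6J (r = 0.404 across genes, rank 1 of 98 arrays).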

How the results depend on the processing

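The settings without arrays that carry markers of another organ, without arrays or genes that stand apart, with control probe sets as covariates, and all settings of the lists but the estimated correlation and fry were chosen after seeing the data. Over all settings, the named genes of the comparisons kept direction and side of the threshold in 1169 values, lost the call in 202, gained it in 1 and changed sign in 17. Called lists did so in 61, 61, 0 and 3 values, and relations in 52, 5, 2 and 5. Of the spread and range values of single genes, 225 stayed within the error and 53 moved, 42 of them with the median absolute deviation in place of the SD. Quantile normalisation on top of the deposited values kept 25 list calls and lost 0, and left 102 values of named genes on their side of the threshold and 2 not.

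The 1099 genes of BXD against AXB with BXA became 385 and 156 below and above the median title number, where fewer families enter, and 635 without arrays that carry markers of another organ, again with fewer families. They became 405 with the Gapdh and 567 with the actin control as a covariate. The cause was not tested. AXB against BXA gave 1 gene instead of 0 above the median title number. The 22 genes of BXH against the classical strains became 58 with arrayWeights, 58 without C57BL/6J and C3H/HeJ, 2 with the title number as a covariate, 0 and 4 below and above its median, and 2 without arrays that carry markers of another organ. The 799 genes of BXH against BXD became 66 without those arrays, where 3 BXH strains stay, and 513 with the Gapdh control. Apart from the fewer strains, the cause was not tested.

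The estimated correlation, which widens the test of a list, left 0 called lists in each of the 4 comparisons, from 6, 6, 6 and 7. Fry called 3, 0 and 0 in BXD against AXB with BXA, AXB against BXA, and BXH against the classical strains. Without arrays that carry markers of another organ the lists called were 1 in AXB against BXA, 0 in BXH against the classical strains and 4 in BXH against BXD. There the airway list turned lower in BXH (adjusted p = 0.117 against the classical strains, 0.581 against BXD), and so did interferon response genes against the classical strains (0.813).

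Some named genes changed sign, none of them called under that setting. Between BXD and AXB with BXA these were Glo1 with the mean over probe sets (0.0301), the title number (0.044), the Gapdh control (0.048) and the actin control (0.049), and Uty with the Gapdh control (0.0203). Below the median title number Eif2s3y turned to -0.054, and above it Apoa2 to 0.0999 and Kdm5d to 0.083. Without arrays that carry markers of another organ Apoa2 turned to 0.27, Hc to 0.085 and Kdm5d to 0.018. In BXH against BXD that setting turned Scgb1a1 to -0.65, Scgb3a1 to -0.46, Scgb3a2 to -0.43, Cyp2f2 to -0.25, Bpifa1 to -0.18 and Sftpd to -0.12, since it removes the arrays in which these transcripts are high. For the others the cause was not tested.

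Without the 2 strains farthest from the median, Nppa with Nppb in BXH turned to r = -0.0338, Nppb with Myh7 in AXB with BXA to 0.103, and fatty acid oxidation with glycolysis to 0.362 in BXD and -0.378 in BXH. Quantile normalisation turned the last to -0.0413. None of these was called before or after, and the cause was not tested.

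The correlation of panel spread with parental difference in BXD, 0.355 at rank 2, was 0.359 with quantile normalisation, 0.398 with the mean over probe sets and 0.334 with the median absolute deviation, each at rank 1. In AXB with BXA it was 0.365 at rank 5 with no filter. The median SD of the classical strains, 0.23, became 0.189 with no filter, 0.208 with the mean over probe sets and 0.212 with the median absolute deviation. The 2064 genes of CAST/EiJ became 496 at a distance of at least 0.5 log2 units, a stricter count by construction. Signal over background could not be computed from summarised values, and differences among genes near 3 log2 units are limited by the floor of the arrays.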

Other observations

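The tests on further probe sets, on the Gapdh control, on the airway list and on the liver list in this part were chosen only after the results were seen. Single arrays carried transcripts of other organs at high levels, given here as values of genes chosen after they were seen. AXB19/PgnJ had the highest mean of the thymus list (7.40, median array 3.997), with the recombinase gene Rag1 at 9.47, the terminal transferase Dntt at 8.53 and the T cell receptor partner Cd8b1 at 9.02. In the same list the thymocyte gene Ptcra stayed between 3.07 and 3.88 on all arrays. BXD14/TyJ had the highest mean of the thyroid list (5.82, median array 3.24), where thyroglobulin Tg peaked at 5.12. The inbred strain 129X1/SvJ had the highest mean of the squamous epithelium list (8.17, median array 3.23), with Krt4 at 11.80, Lor at 10.38 and Ada at 11.51.

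Ucp1, the uncoupling protein of brown fat, varied in every panel, from 3.10 to 10.50 over all arrays. It lay above the parental midpoint in 13 of 29 BXD, 12 of 26 AXB and BXA and 6 of 11 BXH families, yet its SD within near-isogenic families (2.61) exceeded that between the classical strains (1.89). The kappa joining segment Igkj1 behaved alike (2.18 and 2.02). These within-family SDs rest on few arrays, the AXB19 strains and the BXD24 pair. The list spread of matrix (0.44), macrophage (0.46) and antioxidant genes (0.30) also lay above all 10000 random lists, and that of glycolysis genes at percentile 43.05.

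BXD differed from AXB with BXA at 1099 genes, such as Hamp2 and Baiap2l1. The highest of the other splits gave 2, and 1 of 100 splits, the real one, gave as many as 1099. This argues against chance, as far as 100 splits can show. Drift along the title numbers is argued against, since 0.878 of the genes stayed called with that covariate and the median size went from 0.2121 to 0.2122. A share of 0.881 had the sign of DBA/2J minus A/J, which inheritance predicts. The Gapdh control was also higher on the DBA/2J array (-0.22) than on that of A/J (-0.37), the direction of the panels. That share therefore cannot tell inheritance from RNA quality. Sequence variants in the probes stay open. Of the further probe sets of called genes, 0.817 had the sign of the panel difference, against 62.4% for uncalled genes. Their median ratio to that difference was 0.484, and 0.419 for uncalled genes. A variant may reach several probe sets, so these values do not decide it. RNA quality also stays open: the Gapdh control differed by 0.086 (permutation p = 0.000300), and with it as a covariate the median ratio of differences was 0.793, the median size went from 0.21 to 0.16 and its SE from 0.0590 to 0.0635. That left 362 of 1099 genes called, through smaller sizes and, to a lesser degree, a larger SE.

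BXH differed from BXD at 799 genes, such as Scgb1a1 and Tyrobp. The highest of the other splits gave 1, and 1 of 100 splits, the real one, gave as many as 799. This argues against chance, as far as 100 splits can show, but not against order or batch. The share of genes with the sign of C3H/HeJ minus DBA/2J was 0.705 (73.0% of the 748 that followed no marker list of another organ), so inheritance and the order or batch of the separate title ranges cannot be told apart. Airway tissue in BXH hearts may account for the airway genes, of which 9 of 9 were higher, among them Scgb1a1 at a mean of 9.59 against 5.30, but their median pairwise correlation of 0.544 over the classical strains had a wide interval (0.167 to 0.791). Outside that list 0.371 of 795 called genes stayed called with the list mean as a covariate, while the median size went from 0.29 to 0.28 and the SE from 0.0779 to 0.0913, so the SE grew more than the size shrank and the share decides nothing. None of the airway genes was tested for a source within the heart.

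CAST/EiJ lay outside the classical range at 2064 genes, and no biological explanation could be tested with 1 array. Liver RNA may account for the genes far above the range, such as Cps1 and Arg1, and Alb (13.09) and Apoa1 (12.40) were abundant. Of the 141 genes at least 1 log2 unit above, 0.553 followed the liver list over the recombinant strains, against 1.21% of all genes. About 99 of the 141 would be expected to follow if liver RNA made their whole rise. The 14 tested members of the list were not left out, and they follow their own mean in part by construction. The array also passed the level for skeletal muscle (Tnnc2 11.95) and airway (Scgb1a1 10.83). As 93 of the 141 followed some organ list, the other tissues may add to these genes. For the 653 genes less than 1 above liver RNA stays open: 0.0168 of them, 11 genes, followed that list, but it reached only 9.13 in the recombinant strains against 11.04 in CAST/EiJ, where about 4 would be expected to follow if liver RNA made their whole rise, so the share decides nothing. Probes that match C57BL/6J and not CAST/EiJ may account for genes below the range, such as Prxl2b, since 0.615 of the genes outside lay below, yet 256 of 496 did so at 0.5 log2 units or more and NZW/LacJ had 73.7% below. Of the further probe sets of genes below, 0.323 were below too, against 9.58% for genes inside the range. These values cannot tell real lower levels from mismatched probes. Whether the transcripts of other organs on this array lower the share of heart transcripts was not tested.

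For the remaining comparisons, BXH against the classical strains gave 22 genes and the highest other split 5 (1 of 100 splits, the real one). Chance is argued against only as far as 100 splits can show. Order or batch is not excluded, since 7 of the 11 BXH arrays precede all classical strains in title number. With that number as a covariate 2 of the 22 stayed called while their median difference kept a ratio of 0.936, and the lower and upper ranges gave 0 and 4 genes with fewer strains, so order stays open. Airway tissue also stays open: without the arrays with markers of another organ, 8 of the 11 BXH arrays among them, 0 of the 22 stayed called with 3 BXH strains left, while all 22 did without the genes that follow such markers. AXB against BXA gave 0 genes in limma (786 at an unadjusted p under 0.05, fry 0 lists), where all 100 splits give as many by construction, so the splits say nothing about chance. Its highest other split gave 25 genes, and what that split separates was not tested.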
